A study of Mus musculus with 12 samples.

How the data were processed

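Brain tissue of mice was taken 28 days after occlusion of the middle cerebral artery, from the lesioned (ipsilateral) and the intact (contralateral) hemisphere of wild-type mice and of mice with doxycycline-inducible Dkk1. Per the labels' protocols, RNA was extracted with Qiazol and a miRNeasy micro kit with DNase treatment, and mRNA libraries were made with the NEBNext Ultra II directional kit. Groups and replicate numbers came from the labels, which give 12 libraries in 4 groups of 3, all from the same sequencing lane. Per the submitters' processing notes, STAR 2.7.0f, HOMER 4.11, DESeq2 and the genome build mm10 were used; their roles, settings and the use of strand in counting are not given in the sources used here.

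The authors deposited a table of raw counts per RefSeq transcript, with 1 transcript for each of 25124 gene symbols, in the layout of HOMER per the file headers. They also deposited a table of TPM for the same libraries. The deposited TPM table holds the same transcript as the count table for 19749 genes (78.6%), and its columns sum to between 4.6403e+05 and 4.807e+05. Within a library TPM times transcript length over count was constant to within 0.0103% (from the 1st to the 99th percentile of genes with the same transcript). The count column of wild-type ipsilateral 1 lacks a name suffix that the other columns carry, and its counts stand in that constant ratio to the TPM column that has it. All tests rest on the deposited counts except for a stated alternative on the deposited TPM. Coordinates are those of the count table (mm10, 1-based). Of the genes, 20867 were protein-coding, 3761 non-coding and 357 pseudogenes.

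Totals were 21209920 to 26911840 counts per library, and 19557 to 20272 genes had at least 1 count. With edgeR 4.0.16 in R 4.3.3, genes were kept by its expression filter (minimum count 10, by group), which left 17612 genes, 15899 of them protein-coding, and libraries were scaled by TMM (factors 0.963 to 1.04). One model of all 12 libraries with 4 groups was fitted with the robust quasi-likelihood method. The contrasts tested were DKK1 against wild type in each hemisphere, lesioned against intact hemisphere in each genotype, and the interaction. Tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Each adjusted p of a gene is edgeR's unless another tool is named.

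Gene lists were tested with camera of limma 3.58.1 on voom values with the preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Each adjusted p of a list is camera's unless stated. The 37 lists fall into themes. Wnt and vessel lists were Wnt/beta-catenin targets, Wnt ligands with receptors and regulators, brain endothelial, blood-brain barrier, endothelial activation and leak, mural cells, and fibroblast and scar matrix. Immune lists were homeostatic microglia, disease-associated microglia, border macrophages and monocytes, complement, MHC and antigen presentation, interferon response, cytokines and chemokines, T and NK cells, B and plasma cells, and neutrophils. Lists of glia, neurons and regions were general astrocyte, reactive astrocyte, oligodendrocyte and myelin, oligodendrocyte precursors, neuron and synapse, excitatory neurons, inhibitory neurons, striatal medium spiny neurons, thalamus and hypothalamus, hippocampus, choroid plexus, and ependymal and cilia. Other lists were erythrocytes, neurogenesis and proliferation, immediate early genes, lipid handling and foam cells, hypoxia and stress, transgene loci, strain-variable genes, and sex genes. Members not among the tested genes were left out, such as the immunoglobulin genes Ighm, Igkc and Iglc2 and the neutrophil genes, of which 5 of 12 were tested.

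Named genes followed a fixed rule. It took Dkk1, and the 10 largest changes each way among genes past the threshold with at least 1 CPM in a group compared and no overlap between the libraries of the groups, leaving out predicted gene models. It also took up to 4 members of each list with the smallest p, of which examples are printed, and the genes of the transgene, strain and sex lists. Where fewer than 5 genes passed in a direction, the 5 with the smallest p were named. Genes left out as predicted models or small RNAs numbered 35 in the lesioned and 24 in the intact genotype comparison, 313 in the wild-type and 520 in the DKK1 lesion comparison. For a gene with 0 counts over a group, the fold is a bound against 3 counts over that group; for 1 to 3 counts, the ratio has an exact (Clopper-Pearson, conditional on the sum) 95% interval. Both cover counting error only. A few genes that the rule takes are not reported here.

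Whether equal replicate numbers mark 1 animal is not in the labels, so the model above has no block. Deviations from the group means of same-numbered libraries of a genotype correlated at 0.487, 0.310 and 0.297 in wild-type and 0.276, 0.125 and 0.105 in DKK1 mice (log2 CPM with a prior count of 2), and of the 6 possible pairings the one by number ranked first in both. With a prior count of 0.5 the 2nd and 3rd DKK1 pairs were at 0.0991 and 0.0816. In DKK1 mice the best partner of contralateral 2 was ipsilateral 3, and that of ipsilateral 3 was contralateral 2, at every prior count tried. Each other library of either genotype had its best partner at its own number. The numbers were taken to pair the libraries by the rank of the whole pairing, though DKK1 pairs 2 and 3 are uncertain. A fit with genotype-by-number blocks (the number as a block in the genotype comparisons) was run beside each result.

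The alternatives were RLE and upper-quartile scaling, no filter and a stricter filter, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1), and fits of the compared groups alone. Others were the replicate number as a fixed or a random block, leaving out each library, a threshold of 0.01, a test against a 1.5-fold change, and for lists fry, RLE scaling, the block and left-out libraries. Further alternatives, chosen after seeing the data, are named in the closing section. The edgeR fit without a block, for each comparison, and 1 camera test were run on simulated data. For the edgeR fits 200 of 17612 genes, each of at least 1 CPM on average, were changed in 1 group, and genes varied independently. Blocks, fry and the estimated correlation were not tested this way. In the data many more genes changed with the lesion, so the shares recovered apply to the simulated setting. Genes changed 2-fold were recovered at 86.6% in the lesioned and 77.6% in the intact genotype comparison, 85.1% in the wild-type and 77.6% in the DKK1 lesion comparison and 76.1% in the interaction. Genes changed 1.5-fold were recovered at 50.7%, 52.2%, 55.2%, 59.7% and 29.9% in the same order. Called without having been changed were 3 of 158, 13 of 164, 2 of 158, 7 of 161 and 4 of 129 genes, also in that order.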

Results

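The series asked what induced dickkopf-1 (DKK1), a secreted antagonist of Wnt signalling, does to the brain after ischemic stroke. RNA sequencing was done on mouse brain tissue taken 28 days after occlusion of the middle cerebral artery (MCAo), a model of stroke. The DKK1 mice carried a tetO-Dkk1 transgene at Hprt, a doxycycline-dependent activator (rtTA) at the ROSA26 locus and a TCF/Lef1-lacZ reporter, and the other mice were wild type (C57BL6/J). All were given doxycycline at 200 mg/kg, and induction began 3 days after MCAo. The ipsilateral (lesioned) and the contralateral (intact) hemisphere of each genotype gave 4 groups of 3 libraries. The labels do not say which libraries came from separate animals, so p-values measure only the spread between these libraries, part of which can be technical.

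Total counts ran from 21209920 (DKK1 contralateral 1) to 26911840 (wild-type contralateral 1), with 19557 to 20272 genes detected per library. The 10 most abundant genes took 2.17% to 2.55% of the counts. Spearman correlations between libraries of 1 group, taken across genes, which are not independent, were 0.987 to 0.997. No pair of libraries matched within sampling noise, at a chi-square of at least 3.95 per degree of freedom. Hemisphere separated the libraries along the first principal component (73.8% of the variance) and genotype along the second (6.92%). Wild-type ipsilateral 1 lay at 70.9 on the first component, among the DKK1 ipsilateral libraries at 62.8, 79.2 and 83.8 and away from the other wild-type ipsilateral libraries at 29.2 and 37.1. Wild-type contralateral 1 lay at −41.2, nearer the lesioned side than the other wild-type contralateral libraries at −72.6 and −63.3. Values below are log2 fold changes ± standard error from edgeR over 3 libraries per group, and levels are library-size-scaled counts (CPM) as mean ± SD (n = 3). For a gene with 1 to 3 counts over a group the ratio of levels is given with its exact 95% counting interval instead.

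Dkk1 (chromosome 19, 30545885 to 30549496, mm10) had 0 counts in all 6 wild-type libraries. The DKK1 contralateral libraries held 13, 5 and 4 counts and the DKK1 ipsilateral libraries 32, 7 and 44. On the lesioned side Dkk1 was at least 27.7-fold higher in DKK1 mice (edgeR adjusted p = 0.0443), against a floor of 3 counts over the wild-type group. The call was lost without DKK1 ipsilateral 3 (adjusted p = 0.135), wild-type ipsilateral 2 (0.121) or wild-type ipsilateral 3 (0.147). On the intact side the bound was at least 8.33-fold higher and did not pass (adjusted p = 0.437), and the difference between hemispheres of DKK1 mice did not pass (1.68 ± 0.73, adjusted p = 0.0944) but did with the genotype-by-number block (adjusted p = 0.0315). Such bounds and counting intervals cover counting error only. Hprt, the purine salvage enzyme whose locus carries the transgene (chromosome X, 52988078 to 53021660), fell in DKK1 mice by 2.21 on the log2 scale on the intact side, from 77.9 ± 2.42 to 16.8 ± 0.954 CPM, and by 2.45 on the lesioned side, from 69.8 ± 2.15 to 12.8 ± 0.773 CPM. Nnt, a mitochondrial transhydrogenase that carries a deletion in C57BL/6J mice, rose on both sides (0.67 ± 0.07 intact, 0.87 ± 0.07 lesioned). The transcript of the ROSA26 locus did not pass in the lesioned (−0.49 ± 0.12, adjusted p = 0.0631) or the intact comparison (−0.26 ± 0.12), nor did its neighbours Setd5 (−0.04) and Thumpd3 (−0.11) on the lesioned side. By edgeR the transgene list thus held 1 gene that rose and 1 that fell on the lesioned side, and its camera call was down (adjusted p = 0.0203, and adjusted p = 0.548 with an estimated correlation), with a median of −0.11 and a mean of 0.93. Of its 5 genes limma-voom called 1 higher and 1 lower, and DESeq2, which gave Dkk1 no value, called 0 higher and 2 lower. Of 5 measured strain-variable genes Nnt was the 1 that passed in either genotype comparison. Their camera call on the intact side (adjusted p = 0.0214, and adjusted p = 0.463 with an estimated correlation) was lost without DKK1 contralateral 2 (0.0504), DKK1 contralateral 3 (0.072) or wild-type contralateral 3 (0.0689). Counts of the Y-linked gene Uty were 405 to 706 and of Xist 15 to 47 in every library, and none of 6 sex genes differed by genotype.

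**Figure D1:**
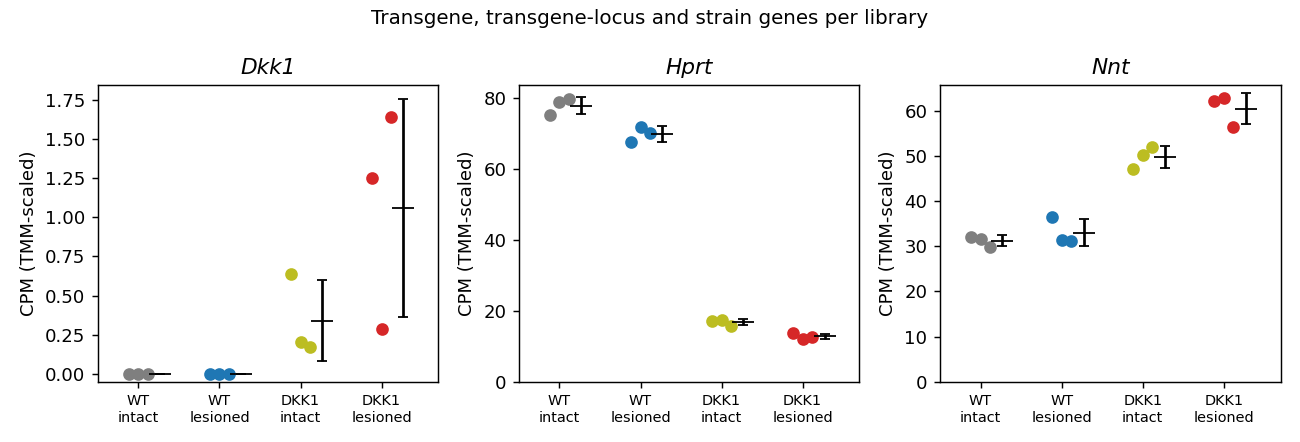
Levels of Dkk1, Hprt and Nnt in CPM (TMM-scaled) in each of the 12 libraries, as 1 point per library, with the mean and SD of each group of 3 as a bar beside the points. Dkk1 lies at 0 in all wild-type libraries, Hprt is lower and Nnt higher in every DKK1 library than in every wild-type library.

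The lesioned hemispheres of the genotypes were compared, since the series asked what induced DKK1 does after stroke. No group carried the transgenes without doxycycline. The comparison thus cannot tell induced DKK1 from the other alleles or other DNA of the DKK1 mice. By camera, limma's competitive list test with a preset correlation, lists of lymphocytes, disease-associated microglia, complement, reactive astrocytes, scar, brain endothelium and endothelial activation were higher in DKK1 mice. None of them passed with the correlation estimated, the smallest value for any list being adjusted p = 0.548 with an estimated correlation. Aspg, a marker of reactive astrocytes, rose by 2.21 ± 0.18, from 41.9 ± 3.5 to 194 ± 44.5 CPM, and the B cell gene Ms4a1 (CD20) rose by 1.53 ± 0.27. The B cell factor Pax5 rose from 5.9 ± 1.13 to 16.7 ± 6.1 CPM. H2-Ea-ps, an alpha chain gene of the class II major histocompatibility complex (MHC) that is silent in C57BL/6 mice (chromosome 17, 34342212 to 34344645), rose by 9.95 ± 0.29, from 0.0632 ± 0.0793 to 68.0 ± 4.3 CPM. Cd5l, a secreted macrophage protein (chromosome 3, 87357881 to 87371074), fell by 4.61 on the log2 scale, from 86.4 ± 72.5 to 3.54 ± 0.0833 CPM.

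Of 17612 genes tested, 417 passed on the lesioned side (edgeR adjusted p under 0.05), 268 higher and 149 lower. The share that was higher was 64.3%, against 50% with upper-quartile scaling and 52.4% on deposited TPM. Among those of at least 1 CPM, 411 of 411 showed no overlap between the groups, as did 20.6% of all tested genes against 10% by chance for 3 libraries against 3. After H2-Ea-ps, the largest rises were in the non-coding RNA Eyelinc18 (8.80 ± 0.35), the histone gene Hist1h2al (8.26 ± 0.35), the non-classical MHC gene H2-T3 (325-fold, 57.9 to 12870), Dkk1, and the pseudogene Tmem181c-ps (6.26 ± 0.21). They were followed by the mast cell tryptase Tpsab1 (from 0.1 ± 0.0942 to 3.93 ± 4.37 CPM), Arhgap8 (4.85 ± 0.26), the serpin Serpina3h (4.72 ± 0.58) and the secreted MHC class I gene H2-Q10 (4.36 ± 0.70). The photoreceptor calcium sensor gene Guca1b had 0 counts over the DKK1 ipsilateral libraries and was at least 36.3-fold lower. After Cd5l, the largest falls were in AA388235 (−4.07 ± 0.32), the acetyltransferase gene Nat8f5 (−3.01 ± 0.56), the incretin receptor Glp1r (−2.78 ± 0.44), Hprt, the ribosomal protein gene Rps3a1 (−2.19 ± 0.08), the microglial receptor Fcrls (−1.86 ± 0.40), the vomeronasal receptor Vmn2r1 (−1.84 ± 0.40) and the adhesion receptor Adgrf4 (−1.66 ± 0.23). Values of the H2, histone, serpin, ribosomal protein and Nat8 families and of pseudogenes are uncertain, since reads of near-identical copies can be split or shared in counting. Chromosome 17, which holds the MHC, held 21.6% of the 417 genes and 5.01% of the genes tested. Of the 50 genes named for this comparison, 10 of them in the closing section, 17 kept the call whichever library was left out: Clec3b, Tfap2b, H2-Ea-ps, Eyelinc18, Hist1h2al, H2-T3, Tmem181c-ps, Arhgap8, Serpina3h, Guca1b, AA388235, Glp1r, Hprt, Rps3a1, Adgrf4, Aspg and Nnt. The others lost it in fits without DKK1 ipsilateral 2 (26 genes, adjusted p 0.0553 to 0.202), DKK1 ipsilateral 3 (28, 0.0512 to 0.178), wild-type ipsilateral 2 (31, 0.0575 to 0.182) or wild-type ipsilateral 3 (32, 0.0521 to 0.204), and without DKK1 ipsilateral 1 for Fcrls and Vmn2r1 (0.052 and 0.0546). The number of called genes itself was 1070 without DKK1 ipsilateral 1, 139 without DKK1 ipsilateral 2, 131 without DKK1 ipsilateral 3, 2551 without wild-type ipsilateral 1, 143 without wild-type ipsilateral 2 and 119 without wild-type ipsilateral 3. It was 655 with the replicate block as a random effect.

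Immune lists fixed before the data were examined were called higher on the lesioned side of DKK1 mice by camera. Of the 417 genes called on this side, 36.5% lay in 10 Mb windows with more intact-side genotype differences than chance gives. These windows held 1290 of the 17612 genes tested. Among these windows were chromosome 17 from 30 to 40 Mb, where H2-Ea-ps lies, and chromosome 3 from 80 to 90 Mb, where Cd5l lies. The list tests were not repeated without the genes of these windows. Whether a member named for a list lies in such a window is not given here. Of T and NK cell genes 2 of 23 rose (8 adjusted over the list alone, median 0.71, adjusted p = 2.51e-07), among them the chemokine receptor Cxcr6 (1.47 ± 0.31) and the CD8 chain Cd8b1 (1.87 ± 0.42). Of B and plasma cell genes 2 of 9 rose (6 adjusted over the list alone, median 1.26, adjusted p = 4.75e-05), the pair named above. Of disease-associated microglia genes 3 of 23 rose (5 adjusted over the list alone, median 0.53, adjusted p = 2.51e-07), which were the lysosomal proteases Ctsd (0.62 ± 0.12) and Ctsb (0.50 ± 0.11) and the lipid carrier Apoe (0.53 ± 0.11). Of complement genes 2 of 13 rose (6 adjusted over the list alone, median 0.52, adjusted p = 3.05e-05), among them C2 (1.07 ± 0.24), whose own call was lost with the replicate number as a block (adjusted p = 0.0645). Of MHC genes 1 of 19 rose (5 rose and 1 fell adjusted over the list alone, median 0.44, adjusted p = 9.98e-05), namely H2-Q4 (1.39 ± 0.27). Of interferon response genes 1 of 26 rose (5 adjusted over the list alone, median 0.52, adjusted p = 1.94e-07), namely the antiviral membrane protein Ifitm3 (0.75 ± 0.15). Among border macrophage and monocyte genes 0 of 17 passed by edgeR (5 at an unadjusted p under 0.05, 1 by limma-voom, 3 by DESeq2, 4 higher adjusted over the list alone, median 0.68, adjusted p = 5.25e-04). Among cytokines and chemokines 0 of 21 passed by edgeR (3 at an unadjusted p under 0.05, 0 by limma-voom, 0 by DESeq2, 0 adjusted over the list alone, median 0.50, adjusted p = 0.00279). With an estimated correlation these lists did not pass: adjusted p = 0.548 with an estimated correlation for all but the MHC list, at 0.592. Homeostatic microglia genes were not called as a list: 1 of 13 fell (1 fell and 1 rose adjusted over the list alone, median 0.24, adjusted p = 0.174), namely Fcrls. Neutrophil genes were not called either: 0 of 5 passed by edgeR (2 at an unadjusted p under 0.05, 0 by limma-voom, 0 by DESeq2, 2 higher adjusted over the list alone, median 0.43, adjusted p = 0.195). Wild-type ipsilateral 1 stood apart within its group, with a T and NK cell score (mean log2 CPM of the members relative to the wild-type intact libraries) of 2.99, against 2.31 and 2.08 in the other wild-type lesions and 3.14 to 3.50 in DKK1 lesions. Its B cell and reactive astrocyte scores also lay below every DKK1 lesion. It lay above DKK1 ipsilateral 1 for disease-associated microglia (3.39 against 3.26) and complement (2.97 against 2.92). The same held for MHC, interferon, cytokine, border macrophage, fibroblast and endothelial activation scores, so these overlapped between the genotypes.

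Reactive astrocyte genes were called higher as a list in DKK1 lesions: 3 of 19 rose (5 adjusted over the list alone, median 0.34, adjusted p = 9.16e-05), namely Aspg, the sphingosine kinase Sphk1 (0.92 ± 0.19) and the intermediate filament vimentin (Vim, 0.46 ± 0.11). Of fibroblast and scar matrix genes 1 of 22 rose (1 adjusted over the list alone, median 0.61, adjusted p = 3.99e-05), namely the matrix protein Thbs2 (1.24 ± 0.26). Of lipid handling genes 1 of 17 rose (9 rose and 2 fell adjusted over the list alone, median 0.34, adjusted p = 0.0204), namely the sterol transporter Abcg1 (0.34 ± 0.08). Of brain endothelial genes 1 of 20 rose (1 adjusted over the list alone, median 0.19, adjusted p = 0.0204), namely the junction protein Pecam1 (0.51 ± 0.08). Of endothelial activation and leak genes 1 of 16 rose (1 adjusted over the list alone, median 0.41, adjusted p = 0.00961), namely the fenestration protein Plvap (0.66 ± 0.13), which was also higher on the intact side. Each of these 5 lists had adjusted p = 0.548 with an estimated correlation, and the brain endothelial call was lost without DKK1 ipsilateral 2 (adjusted p = 0.0668). Blood-brain barrier genes were not called as a list: 1 of 20 fell (1 fell and 1 rose adjusted over the list alone, median 0.05, adjusted p = 0.646). Nor were mural cell genes: 1 of 15 rose (2 adjusted over the list alone, median 0.13, adjusted p = 0.0872), namely smooth muscle myosin Myh11 (0.52 ± 0.11). The limit given for the immune lists, that genes of the windows were not left out, holds for the lists of this paragraph too.

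Targets of Wnt/beta-catenin signalling, the pathway that DKK1 blocks, did not pass as a list between the lesioned hemispheres: 1 of 20 rose (3 adjusted over the list alone), with a median of 0.09 and camera adjusted p = 0.496. The member that rose was Dkk2 (0.89 ± 0.20), itself a modulator of Wnt receptors. Of Wnt ligands, receptors and regulators 0 of 47 passed by edgeR (12 at an unadjusted p under 0.05, 1 by limma-voom, 3 by DESeq2, 0 adjusted over the list alone, median 0.11, adjusted p = 0.207). Lists of neurons and synapses, striatal neurons, general astrocytes and myelin were not called on the lesioned side. Of neuron and synapse genes 0 of 24 passed by edgeR (2 at an unadjusted p under 0.05, 0 by limma-voom, 0 by DESeq2, 0 adjusted over the list alone, median −0.02, adjusted p = 0.202). Of striatal medium spiny neuron genes 0 of 18 passed by edgeR (0 at an unadjusted p under 0.05, 0 by limma-voom, 0 by DESeq2, 0 adjusted over the list alone, median −0.08, adjusted p = 0.222). Of general astrocyte genes 0 of 13 passed by edgeR (1 at an unadjusted p under 0.05, 0 by limma-voom, 1 by DESeq2, 0 adjusted over the list alone, median −0.04, adjusted p = 0.209). Of myelin genes 0 of 16 passed by edgeR (1 at an unadjusted p under 0.05, 0 by limma-voom, 0 by DESeq2, 0 adjusted over the list alone, median −0.01, adjusted p = 0.364). Markers of other brain regions moved beside the immune lists. Thalamus and hypothalamus genes were called lower in DKK1 lesions as a list: 0 of 16 passed by edgeR (3 at an unadjusted p under 0.05, 0 by limma-voom, 2 by DESeq2, 2 lower adjusted over the list alone, median −0.24, adjusted p = 0.0203), with adjusted p = 0.621 with an estimated correlation. Choroid plexus genes were called lower as well: 0 of 13 passed by edgeR (0 at an unadjusted p under 0.05, 0 by limma-voom, 0 by DESeq2, 0 adjusted over the list alone, median −0.38, adjusted p = 0.0362), with adjusted p = 0.721 with an estimated correlation. The thalamus call was lost without DKK1 ipsilateral 2 (adjusted p = 0.218), wild-type ipsilateral 1 (0.0585) or wild-type ipsilateral 3 (0.208). The choroid plexus call was lost without DKK1 ipsilateral 1 (0.374), DKK1 ipsilateral 2 (0.176) or wild-type ipsilateral 1 (0.576), and with the replicate number as a block (0.0555). Median, mean and camera direction differed in sign for lists that were not called: oligodendrocyte precursors, neurogenesis and proliferation, and sex genes.

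**Figure D2:**
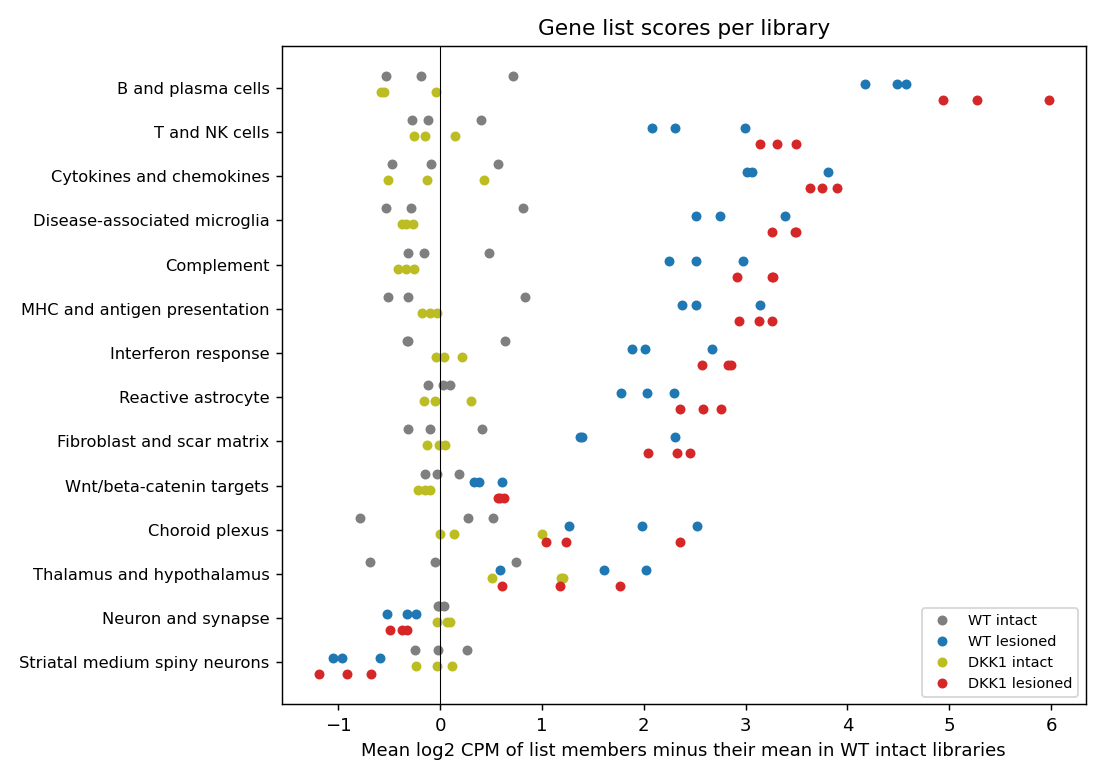
Score of 14 gene lists in each of the 12 libraries, as the mean log2 CPM of the list's members minus their mean in the wild-type intact libraries (x axis), with 1 point per library and colours for the 4 groups. T and NK cell scores lie at 3.14 to 3.50 in DKK1 lesions and at 2.08 to 2.99 in wild-type lesions, while neuron and synapse scores lie below 0 in every lesioned library of both genotypes. Disease-associated microglia scores overlap, at 3.26 to 3.50 in DKK1 lesions and 2.51 to 3.39 in wild-type lesions.

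The intact hemispheres were compared as the background to the lesioned side. Genes with the largest changes included gene clusters on chromosome 17 and transcripts of the liver. The serine protease genes Prss33 (3.97 ± 0.46), Prss41 (3.60 ± 0.30) and Prss32 (2.89 ± 0.50), neighbours on chromosome 17, rose in DKK1 mice, while the MHC genes H2-Bl (−2.68 ± 0.39), H2-K2 (−2.65 ± 0.32) and H2-DMb1 (−2.46 ± 0.40) fell. Plvap, a protein of fenestrated endothelium, rose (0.88 ± 0.13, adjusted p = 0.00461). Albumin mRNA (Alb) fell by 4.29 on the log2 scale, from 41.7 ± 42.1 to 2.11 ± 0.452 CPM.

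On the intact side 155 of 17612 genes passed (edgeR), 65 higher and 90 lower. At 1 CPM or more, 150 of 150 showed no overlap between the groups, as did 11.9% of all tested genes against 10% by chance. The largest rises were in Hist1h2al (407-fold, 112 to 3363), Eyelinc18 (7.08 ± 0.33), Tmem181c-ps (6.93 ± 0.22), Serpina3h (5.79 ± 0.84), Arhgap8 (4.31 ± 0.27), the Prss genes above, the ring finger gene Rnf151 (3.47 ± 0.47) and perinatal myosin Myh8 (2.88 ± 0.32). The largest falls were in Guca1b (at least 38.0-fold lower), AA388235 (−5.94 ± 0.40), the liver genes Bhmt (−5.25 ± 1.01), Serpina3k (−5.04 ± 0.92), Alb and Apoa1 (−4.12 ± 0.82), the cytokinesis gene Prc1 (−2.78 ± 0.29) and the MHC genes above. The non-classical MHC gene H2-T23 (−0.98 ± 0.17) also fell. Reads of the Prss, serpin, histone and H2 families may have been shared among copies. Chromosome 17 held 65 of the 155 genes (41.9%) and 5.01% of the genes tested. The liver genes followed single libraries: Alb had 2341, 742 and 129 counts in wild-type contralateral 1, 2 and 3. Without 1 library, 17 of the 24 genes named here kept the call each time. Alb, Apoa1, Bhmt, Serpina3k, Prss32, H2-DMb1 and H2-T23 lost it without DKK1 contralateral 1 (adjusted p 0.059 to 0.222), DKK1 contralateral 2 (0.0671 to 0.204) or DKK1 contralateral 3 (0.052 to 0.204). Apoa1, Prss32 and H2-T23 also lost it without wild-type contralateral 1 (0.0747 to 0.0803), and Alb, Apoa1 and H2-T23 without wild-type contralateral 2 (0.0545 to 0.089). With the replicate number as a block Alb (0.0519), Apoa1 (0.0646) and H2-T23 (0.0526) did not pass. The count was 94 without DKK1 contralateral 1, 99 without DKK1 contralateral 2 and 100 without DKK1 contralateral 3.

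Few lists differed between the intact hemispheres. Thalamus and hypothalamus genes were called higher in DKK1 mice as a list: 0 of 16 passed by edgeR (3 at an unadjusted p under 0.05, 0 by limma-voom, 0 by DESeq2, 0 adjusted over the list alone, median 0.52, adjusted p = 0.00137). Complement genes were called lower: 0 of 13 passed by edgeR (2 at an unadjusted p under 0.05, 0 by limma-voom, 0 by DESeq2, 0 adjusted over the list alone, median −0.32, adjusted p = 0.0214). So were Wnt/beta-catenin targets, where 0 of 20 passed by edgeR (0 at an unadjusted p under 0.05, 0 by limma-voom, 0 by DESeq2, 0 adjusted over the list alone, median −0.15, adjusted p = 0.0332). Also lower were blood-brain barrier genes, where 0 of 20 passed by edgeR (2 at an unadjusted p under 0.05, 0 by limma-voom, 0 by DESeq2, 0 adjusted over the list alone, median −0.09, adjusted p = 0.0214). With an estimated correlation none passed: adjusted p = 0.988 with an estimated correlation for thalamus and complement, 0.831 for Wnt targets and 0.463 for barrier genes. The Wnt target call was lost without DKK1 contralateral 2 (0.0712), DKK1 contralateral 3 (0.186) or wild-type contralateral 1 (0.446). The barrier call was lost without DKK1 contralateral 3 (0.107) or wild-type contralateral 1 (0.075), and the complement call without the same libraries (0.0674 and 0.446). In all 5 lists were called. With the replicate number as a block 8 were, which added homeostatic microglia (adjusted p = 0.0233), general astrocyte (0.024) and immediate early genes (0.0233), each lower in DKK1 mice. The number was 10, 1, 8 and 9 without DKK1 contralateral 1, DKK1 contralateral 3, wild-type contralateral 1 and wild-type contralateral 2. MHC genes were not called (2 of 19 fell, H2-DMb1 and H2-T23, and 2 fell and 2 rose adjusted over the list alone), where the median (−0.01) lay below 0 and the camera direction was up (adjusted p = 0.963). Signs of median, mean and camera direction also differed for the uncalled lists of endothelial activation, interferon response, reactive astrocyte, oligodendrocyte precursor, Wnt ligand, hypoxia, transgene and sex genes.

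**Figure D3:**
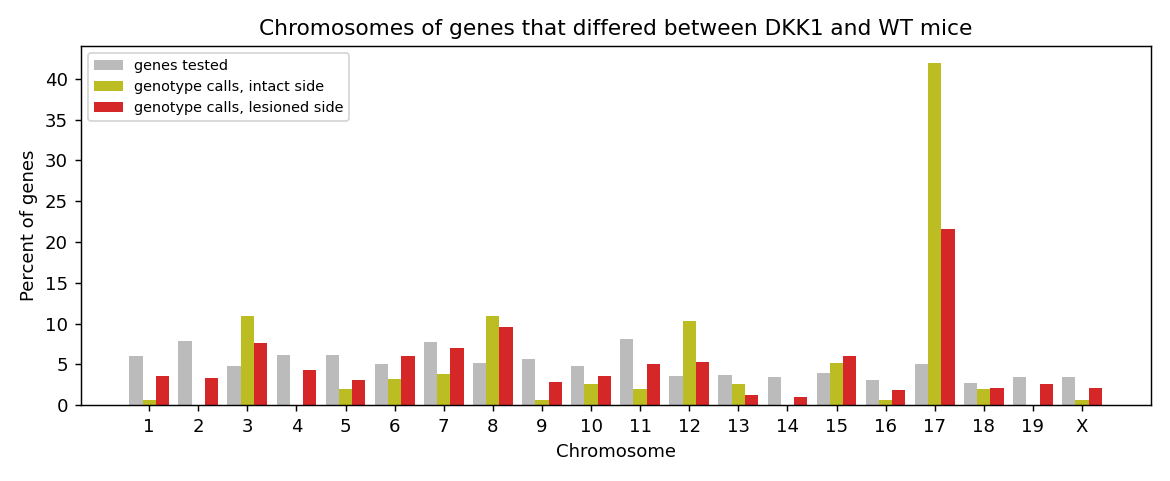
Percent of the 17612 genes tested, of the 155 genes that differed by genotype on the intact side and of the 417 that did on the lesioned side, for each chromosome (bars from 0). Chromosome 17 holds 5.01% of the genes tested, 41.9% of the intact-side genes and 21.6% of the lesioned-side genes.

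Lesioned and intact hemispheres of wild-type mice were compared to describe the stroke response at 28 days. By camera, lists of microglia, lymphocytes, reactive astrocytes and scar were higher in the lesioned hemisphere, and lists of striatal and other neurons lower. No list passed with the correlation estimated (smallest adjusted p = 0.202 with an estimated correlation). The complement gene C1qb (2.17 ± 0.14) and the lipid carrier Apoe (1.46 ± 0.12) rose, as did the B cell gene Ms4a1 (5.56 ± 0.46), the T cell receptor subunit Cd3e (4.39 ± 0.36) and the matrix proteoglycan decorin (Dcn, 2.93 ± 0.31). The dopamine receptor Drd2 (−1.21 ± 0.19) and the adenosine receptor Adora2a (−1.15 ± 0.19) of striatal neurons fell.

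In wild-type mice 6546 genes passed, 3740 higher and 2806 lower. Of 6330 called genes with at least 1 CPM, 6132 showed no overlap between the hemispheres, as did 50.3% of all tested genes against 10% by chance. The largest rises were in the metalloproteinase gene Mmp27 (at least 47.6-fold), the growth factor Gdf3 (at least 27.7-fold), the pyrin gene Mefv (109-fold, 37.0 to 531), the C-type lectin Clec4d (99.9-fold, 33.9 to 487), and the mast cell protease Mcpt4 (106-fold, 18.7 to 4241). Next were Cd5l (6.17 ± 0.91), the chemokine Ccl4 (80.1-fold, 27.1 to 391), the lymphocyte GTPase Gimap7 (94.2-fold, 16.5 to 3758), the nucleoside transporter Slc28a2 (77.2-fold, 21.05 to 643) and the B cell lectin Siglecg (6.02 ± 0.55). The Mcpt4 call was lost without wild-type contralateral 2 (adjusted p = 0.0607), wild-type contralateral 3 (0.057) or wild-type ipsilateral 1 (0.0742), and its log2 change was 2.92 in the last fit. The other 49 genes named for this comparison kept their calls whichever library was left out. The 10 largest falls were all in genes of the liver: Mat1a (−4.19 ± 1.03), Serpina3k (−4.15 ± 0.83), Gc (−4.10 ± 0.90), Fgb (−3.89 ± 0.89), Apoa1 (−3.77 ± 0.79), Serpina1b (−3.76 ± 0.85), Serpina1a (−3.73 ± 0.87), Fga (−3.10 ± 0.78), Cps1 (−3.06 ± 0.78) and Cyp2a5 (−2.92 ± 0.70). Albumin stood at 87.8, 31.7 and 5.45 CPM in wild-type contralateral 1, 2 and 3, at 6.65 CPM in wild-type ipsilateral 1, and had 33 to 82 counts in each other library.

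**Figure D4:**
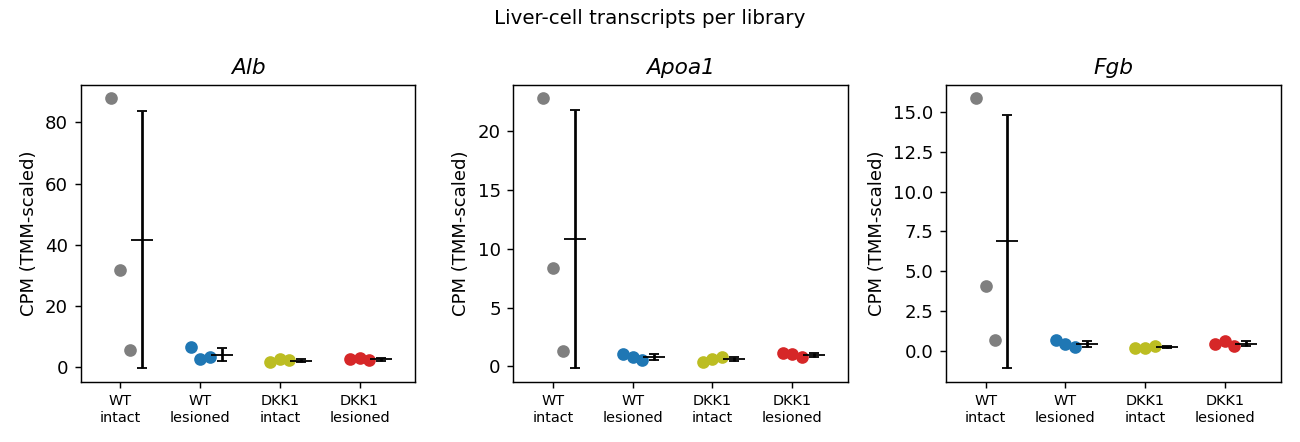
Levels of the liver transcripts Alb, Apoa1 and Fgb in CPM (TMM-scaled) in each of the 12 libraries, as 1 point per library, with the mean and SD of each group of 3 as a bar beside the points. Alb reaches 87.8 CPM in wild-type contralateral 1 and 31.7 CPM in wild-type contralateral 2.

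Each list of immune cells or immune signals was called higher in wild-type lesions by camera, with adjusted p = 0.202 or more with an estimated correlation. All members rose in the lists of disease-associated microglia (23 of 23, median 2.58, adjusted p = 3.81e-14, the protease Ctsd at 1.53 ± 0.13), complement (13 of 13, 2.31, 6.65e-11, C4b at 2.31 ± 0.15), MHC (19 of 19, 2.57, 2.78e-12), interferon response (26 of 26, 2.04, 2.23e-12), B and plasma cells (9 of 9, 4.89, 7.90e-06) and neutrophils (5 of 5, 2.98, 0.00132), over all genes and adjusted over the list alone. Of cytokines and chemokines 19 of 21 rose (20 adjusted over the list alone, median 3.64, adjusted p = 1.24e-09), among them Cxcl1 (4.93 ± 0.35) and Cxcl13 (5.77 ± 0.56). Of T and NK cell genes 20 of 23 rose and 1 fell (20 and 1 adjusted over the list alone, median 3.54, adjusted p = 6.82e-07). Of border macrophage and monocyte genes 14 of 17 rose (14 rose and 1 fell adjusted over the list alone, median 2.17, adjusted p = 1.53e-05). Of homeostatic microglia genes 10 of 13 rose (10 adjusted over the list alone, median 1.12, adjusted p = 7.41e-06), among them the growth factor receptor Csf1r (1.41 ± 0.14). Of reactive astrocyte genes 17 of 19 rose (17 adjusted over the list alone, median 1.87, adjusted p = 5.49e-10), among them Serpina3n (2.86 ± 0.25), Aspg (2.74 ± 0.21) and Vim (1.91 ± 0.11). General astrocyte genes were not called as a list: 4 of 13 rose (4 adjusted over the list alone, median 0.14, adjusted p = 0.161). Of fibroblast and scar matrix genes 18 of 22 rose (20 adjusted over the list alone, median 1.66, adjusted p = 2.12e-07), among them periostin (Postn, 2.64 ± 0.22). Of endothelial activation genes 12 of 16 rose (13 adjusted over the list alone, median 1.63, adjusted p = 3.55e-04), among them the adhesion molecules Icam1 (2.77 ± 0.27) and Vcam1 (1.31 ± 0.17). Of blood-brain barrier genes 10 of 20 rose (11 adjusted over the list alone, median 0.29, adjusted p = 0.00123), among them the junction protein F11r (1.64 ± 0.21). Of mural cell genes 6 of 15 rose (7 adjusted over the list alone, median 0.35, adjusted p = 0.0112). Brain endothelial genes were not called as a list: 4 of 20 rose (4 adjusted over the list alone, median 0.10, adjusted p = 0.0567). With the genotype-by-number block this list was called (9 of 20 rose, adjusted p = 0.0118, and adjusted p = 0.245 with an estimated correlation). Of Wnt/beta-catenin targets 6 of 20 rose and 1 fell (6 and 1 adjusted over the list alone, median 0.23, adjusted p = 0.024), among them Dkk2 (2.39 ± 0.23). The call of this list, not that of Dkk2, was lost without wild-type ipsilateral 1 (adjusted p = 0.0603). Of lipid handling genes 11 of 17 rose and 5 fell (11 and 6 adjusted over the list alone, median 0.94, adjusted p = 0.0268), among them the cholesterol exporter Abca1 (2.50 ± 0.21). Of myelin genes 13 of 16 rose (13 adjusted over the list alone, median 0.46, adjusted p = 3.39e-05). Of oligodendrocyte precursor genes 6 of 11 rose (7 adjusted over the list alone, median 0.36, adjusted p = 0.00635).

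Neuronal lists were called lower in wild-type lesions. Of neuron and synapse genes 20 of 24 fell (23 adjusted over the list alone, median −0.33, adjusted p = 6.72e-10), among them Shank3 (−0.47 ± 0.07) and Nrgn (−0.61 ± 0.10). Of striatal medium spiny neuron genes 16 of 18 fell (17 adjusted over the list alone, median −0.84, adjusted p = 2.52e-09), among them the retinoid receptor Rxrg (−1.27 ± 0.20). Of excitatory neuron genes 9 of 13 fell (10 adjusted over the list alone, median −0.43, adjusted p = 9.27e-05). Of inhibitory neuron genes 1 of 11 rose and 8 fell (1 and 8 adjusted over the list alone, median −0.28, adjusted p = 0.00603). Lists of other regions were called higher beside them. Of thalamus and hypothalamus genes 8 of 16 rose and 1 fell (10 and 1 adjusted over the list alone, median 1.23, adjusted p = 0.00933), among them Prkcd (1.44 ± 0.28) and oxytocin (Oxt, 4.24 ± 1.05). Of choroid plexus genes 13 of 13 rose (13 adjusted over the list alone, median 2.03, adjusted p = 1.23e-04), among them the water channel Aqp1 (2.35 ± 0.49). Of ependymal and cilia genes 12 of 12 rose (12 adjusted over the list alone, median 1.27, adjusted p = 6.63e-05), among them Foxj1 (1.36 ± 0.16). Hippocampus genes were not called: 4 of 11 rose (4 adjusted over the list alone, median 0.43, adjusted p = 0.267). With an estimated correlation no list passed in this comparison, the smallest value being adjusted p = 0.202 with an estimated correlation.

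The same comparison in DKK1 mice described the stroke response with DKK1 induced. By camera, lists of microglia, lymphocytes, reactive astrocytes and scar were again higher in the lesioned hemisphere, and neuronal lists lower. No list passed with the correlation estimated (smallest adjusted p = 0.241 with an estimated correlation). The B cell gene Ms4a1 (803-fold, 144 to 31744) and the T cell gene Cd3e (5.48 ± 0.36) rose, and C1qb (2.95 ± 0.15), Apoe (1.99 ± 0.12) and Aspg (4.32 ± 0.21) rose. The striatal genes Drd2 (−1.27 ± 0.19) and Rxrg (−1.26 ± 0.20) fell.

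In DKK1 mice 8819 genes passed, 4846 higher and 3973 lower. The share that was higher was 54.95%, against 48.4% with upper-quartile scaling, 52.6% with RLE scaling and 56.5% on deposited TPM. Of 8566 called genes with at least 1 CPM, 8385 showed no overlap, as did 59.9% of all tested genes against 10% by chance. Among the largest rises were the B cell kinase gene Blk (at least 182-fold), the endolysosomal channel Mcoln3 (at least 143-fold), the lymphocyte receptor P2ry10 (at least 116-fold), and the lectins Clec4d (at least 115-fold) and Clec4e (at least 67.8-fold). Next were Gimap7 (at least 74.1-fold), the proton pump subunit Atp6v0d2 (9.97 ± 1.14), Ms4a1 and the apolipoprotein Apoc2 (790-fold, 141 to 31221). Among the largest falls were the transcription factor Tfap2d (−3.54 ± 0.83), the peroxidase Gpx6 (−2.03 ± 0.47), the receptor Gpr139 (−1.99 ± 0.30), the Wnt ligand Wnt8b (−1.79 ± 0.52), and Vmn2r85 (−1.79 ± 0.41). Next were the retinoid isomerase Rpe65 (−1.78 ± 0.41), the collagen Col24a1 (−1.71 ± 0.27), the checkpoint gene Clspn (−1.67 ± 0.29) and Tspear (−1.57 ± 0.42). Hprt and Nnt differed slightly between hemispheres (−0.39 ± 0.06 and 0.28 ± 0.07). Each of the 40 genes named for this comparison kept its call whichever library was left out.

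All members rose again in the disease-associated microglia (median 3.17, adjusted p = 1.70e-11, Ctsd at 2.18 ± 0.13), complement (3.04, 2.25e-09), MHC (2.95, 4.52e-10), interferon (2.69, 2.41e-11), B cell (6.78, 2.56e-05) and neutrophil lists (3.18, 0.00245), over all genes and adjusted over the list alone, and both last medians were the same with members at 0 counts set to their bounds. Of T and NK cell genes 20 of 23 rose and 1 fell (20 and 1 adjusted over the list alone, median 4.96, adjusted p = 1.95e-07). Of cytokines and chemokines 20 of 21 rose (20 adjusted over the list alone, median 4.31, adjusted p = 8.12e-08). Of border macrophage genes 13 of 17 rose (14 adjusted over the list alone, median 2.80, adjusted p = 1.16e-05). Of homeostatic microglia genes 11 of 13 rose (12 adjusted over the list alone, median 1.71, adjusted p = 2.12e-05). Of reactive astrocyte genes 18 of 19 rose (18 adjusted over the list alone, median 2.24, adjusted p = 5.25e-09), with Vim (2.42 ± 0.11). Of fibroblast and scar genes 19 of 22 rose (20 adjusted over the list alone, median 2.25, adjusted p = 8.50e-08), with Dcn (3.99 ± 0.32) and the crosslinking enzyme Lox (4.65 ± 0.42). Of brain endothelial genes 10 of 20 rose (12 adjusted over the list alone, median 0.45, adjusted p = 0.0018), with Pecam1 (0.96 ± 0.08). Of endothelial activation genes 13 of 16 rose and 1 fell (13 and 2 adjusted over the list alone, median 2.08, adjusted p = 0.00205). Of blood-brain barrier genes 11 of 20 rose (11 adjusted over the list alone, median 0.45, adjusted p = 0.001), with claudin-5 (Cldn5, 0.54 ± 0.07). Of mural cell genes 8 of 15 rose (8 adjusted over the list alone, median 0.52, adjusted p = 0.00245). Of Wnt/beta-catenin targets 9 of 20 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.43, adjusted p = 0.00804), with Dkk2 (3.66 ± 0.24). Of lipid handling genes 11 of 17 rose and 5 fell (11 and 5 adjusted over the list alone, median 1.22, adjusted p = 0.0266). Of myelin genes 11 of 16 rose (11 adjusted over the list alone, median 0.38, adjusted p = 0.00244). Of oligodendrocyte precursor genes 5 of 11 rose (5 adjusted over the list alone, median 0.30, adjusted p = 0.046), a call lost without DKK1 contralateral 2 (0.0576), DKK1 contralateral 3 (0.0544) or DKK1 ipsilateral 1 (0.123).

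Of neuron and synapse genes 24 of 24 fell (24 adjusted over the list alone, median −0.41, adjusted p = 1.90e-09) in DKK1 lesions, with Shank3 (−0.54 ± 0.07). Of striatal neuron genes 17 of 18 fell (18 adjusted over the list alone, median −0.89, adjusted p = 1.80e-07). Of excitatory neuron genes 11 of 13 fell (11 adjusted over the list alone, median −0.57, adjusted p = 1.11e-04). Of inhibitory neuron genes 7 of 11 fell (10 adjusted over the list alone, median −0.44, adjusted p = 0.00146). Thalamus and hypothalamus genes were not called: 1 of 16 rose and 2 fell (1 and 2 adjusted over the list alone, median 0.24, adjusted p = 0.967), with Prkcd (1.07 ± 0.28) higher and Rora (−0.46 ± 0.06) and Ntng1 (−0.65 ± 0.14) lower. The camera direction was down although median and mean lay above 0. Of choroid plexus genes 3 of 13 rose (2 adjusted over the list alone, median 1.22, adjusted p = 0.046), with Aqp1 (2.16 ± 0.49), a call lost without DKK1 contralateral 1 (0.0726), DKK1 contralateral 3 (0.0642) or DKK1 ipsilateral 3 (0.202). Of ependymal and cilia genes 5 of 12 rose (5 adjusted over the list alone, median 0.82, adjusted p = 0.00731). Hippocampus genes were not called: 1 of 11 fell (0 adjusted over the list alone, median 0.21, adjusted p = 0.94), also with a camera direction of down against a median and mean above 0. The signs differed too for the uncalled erythrocyte and transgene lists in this comparison, and for strain-variable genes in wild-type mice. The smallest value for any list was adjusted p = 0.241 with an estimated correlation.

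The lesion responses of the genotypes shared most of their genes, including the immune and neuronal genes above. Called higher in both were 3390 genes (1029 for independent lists), lower in both 2421 (633) and in opposite directions 4. Log2 changes correlated across genes, which are not independent (Pearson r 0.886, Spearman 0.845). Of the shared genes 83.1% had the larger change in DKK1 mice (median ratio 1.29). Single libraries can move that share, as wild-type lesions lay at 29.2, 37.1 and 70.9 on the first component. Genotype differences of the brain sides were shared too, among them Hprt, Nnt, Plvap, Guca1b and Hist1h2al: 52 were higher on both sides (0.989 for independent lists) and 62 lower (0.761). Their log2 changes correlated weakly (Pearson r 0.317, Spearman 0.0991), and 303 were called on the lesioned and 41 on the intact side alone, which does not show that they differ between sides.

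The interaction of genotype and hemisphere tested whether the lesion response, the log2 change of lesioned over intact tissue, differed by genotype. Values above 0 stand for a higher and below 0 for a lower response in DKK1 mice, which can also be a larger fall. A single gene passed, the MHC class I gene H2-T-ps, a pseudogene by its symbol (chromosome 17, 36109030 to 36111676). Its lesion response was higher in DKK1 mice by 2.63 ± 0.28 (edgeR adjusted p = 0.0148). It stood at 1.66 ± 0.234 CPM in intact and 1.85 ± 0.279 CPM in lesioned wild-type tissue, and at 1.02 ± 0.0963 and 7.04 ± 1.01 CPM in DKK1 tissue. Its annotation is protein-coding, and its reads are uncertain, as its family has close copies. By camera, lists of lymphocytes, microglia, complement, scar and brain endothelium had higher lesion responses in DKK1 mice. Lists of thalamus, choroid plexus and hippocampus had lower ones. Their genes were higher in intact (medians 0.52, 0.32 and 0.25) and lower in lesioned DKK1 than wild-type tissue (−0.24, −0.38 and −0.20). The smallest adjusted p was 0.629 with an estimated correlation (0.126 with the fixed block as well), so 0 lists passed. By fry, which tests whether the genes of a list move one way on balance and not against other genes, 0 lists passed without the block. With the fixed block, chosen after seeing the data, 15 passed by fry, 13 higher and 2 lower, from complement (adjusted p = 0.0142) to thalamus and hypothalamus (0.0453).

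Besides H2-T-ps, 0 genes passed by edgeR, 1689 genes had an unadjusted p under 0.05, and limma-voom called 0 genes and DESeq2 70. Of the DESeq2 calls among the genes that edgeR tested, 82.6% were higher in DKK1 mice, against 100% for edgeR. With the genotype-by-number block as a fixed effect 288 genes passed, of which 30 had lower and the others higher lesion responses in DKK1 mice. This count rests on the pairing by number, and DKK1 pairs 2 and 3 are uncertain. With the same block as a random effect 2 genes passed, and with the number alone as a block, a fit chosen after seeing the data, 2. The H2-T-ps call was lost without DKK1 contralateral 1 (adjusted p = 0.101), 2 (0.0842) or 3 (0.122), DKK1 ipsilateral 2 (0.0858) or 3 (0.0919), or wild-type ipsilateral 2 (0.0677), each of which left 0 calls. The count was 17 without DKK1 ipsilateral 1, 2 without wild-type contralateral 1, 4 without wild-type contralateral 3 and 393 without wild-type ipsilateral 1. Among genes that did not pass, those with the smallest p and higher lesion responses in DKK1 mice were the MHC genes H2-Bl (3.63 ± 0.50) and H2-T9 (1.02 ± 0.17), the gap junction gene Gjb2 (1.28 ± 0.21) and the complement gene C4a (1.64 ± 0.27), at adjusted p from 0.101 to 0.202. Those with lower responses were the imprinted non-coding RNA Kcnq1ot1 (−0.64 ± 0.11), Lrrc55 (−0.71 ± 0.12), the axon guidance gene Ntng1 (−1.05 ± 0.19), the channel subunit Kcng4 (−0.70 ± 0.14) and Cntnap5a (−0.52 ± 0.11), at adjusted p from 0.202 to 0.311. With the fixed block each of these genes but Kcng4 passed, at adjusted p from 0.00208 (Ntng1) to 0.0474 (Cntnap5a). Kcnq1ot1 lies antisense within Kcnq1, so its reads are uncertain, since the use of strand in counting is not given in the sources used here.

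By camera 15 lists had higher and 5 lower lesion responses in DKK1 mice. The neuron and synapse and the inhibitory neuron lists, among the 5, were called lower with the lesion in both genotypes, with medians of −0.33 and −0.28 in wild-type and −0.41 and −0.44 in DKK1 lesions. By edgeR and limma-voom 0 members of the 20 lists passed over all genes, while DESeq2 called 2 complement genes and 1 gene each of the MHC, brain endothelial, reactive astrocyte and thalamus lists. At an unadjusted p under 0.05 were 10 of 23 disease-associated microglia, 8 of 13 complement and 5 of 9 B and plasma cell genes. All lists had adjusted p = 0.629 or more with an estimated correlation. Lists that kept the call whichever library was left out were T and NK cells (median 1.03, adjusted p = 9.92e-04, 0 of 23 members adjusted over the list alone), disease-associated microglia (0.70, 1.05e-06, 0 of 23), complement (0.82, 8.31e-07, 8 of 13 higher), reactive astrocytes (0.42, 0.00725, 3 of 19), brain endothelium (0.23, 0.00125, 1 of 20) and thalamus and hypothalamus (−0.97, 1.05e-06, 1 of 16 lower).

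Without wild-type contralateral 1 the calls were lost for B and plasma cells (median 1.51, adjusted p = 0.013, 3 of 9 higher adjusted over the list alone, 0.213 without the library), MHC (0.51, 0.00339, 2 of 19, 0.436), border macrophages (0.70, 0.0174, 0 of 17, 0.225), interferon response (0.54, 0.00147, 0 of 26, 0.284), homeostatic microglia (0.39, 0.00372, 0 of 13, 0.205), fibroblast and scar (0.67, 0.00124, 0 of 22, 0.0534), lipid handling (0.32, 0.0288, 0 of 17, 0.286, and 0.0806 without wild-type ipsilateral 2) and mural cells (0.18, 0.00938, 0 of 15, 0.181, and 0.0661 without DKK1 ipsilateral 1). Wnt/beta-catenin targets had a median of 0.21 (adjusted p = 0.0288, 0 of 20 members by either adjustment), a call lost with the block (0.0622) and without DKK1 contralateral 3 (0.1), DKK1 ipsilateral 1 (0.117), wild-type contralateral 1 (0.225) or wild-type ipsilateral 2 (0.0754). Blood-brain barrier genes had a median of 0.16 (adjusted p = 0.0288, 2 of 20 higher adjusted over the list alone), lost with the block (0.0652) and without DKK1 contralateral 3 (0.0829), DKK1 ipsilateral 1 (0.067), wild-type contralateral 1 (0.1) or wild-type ipsilateral 3 (0.0564). Choroid plexus genes (−0.65, 0.00339, 0 of 13 by either adjustment) lost the call without DKK1 contralateral 2 (0.137), DKK1 ipsilateral 1 (0.067), wild-type contralateral 2 (0.0708) or wild-type ipsilateral 1 (0.0851). Hippocampus genes (−0.22, 0.0108, 2 of 11 lower adjusted over the list alone) lost it without DKK1 contralateral 2 (0.178) or DKK1 ipsilateral 1 (0.067). Inhibitory neuron genes (−0.16, 0.0288, 0 of 11 by either adjustment) lost it without DKK1 contralateral 1 (0.0684) or 3 (0.0829), DKK1 ipsilateral 3 (0.0731), wild-type contralateral 1 (0.0604) or 3 (0.0618) or wild-type ipsilateral 2 (0.21). Neuron and synapse genes (−0.06, 0.00938, 0 of 24 by either adjustment) lost it without DKK1 ipsilateral 3 (0.14) or wild-type ipsilateral 2 (0.39). In all 20 lists were called, and 12 without wild-type contralateral 1. That library had a disease-associated microglia score of 0.81, against −0.53 and −0.28 in the other wild-type intact libraries. Signs of median, mean and camera direction differed for the uncalled lists of oligodendrocyte precursor, immediate early, transgene and sex genes. With the block endothelial activation genes (adjusted p = 0.0261, and adjusted p = 0.228 with an estimated correlation) were called as higher in DKK1 mice. Erythrocyte genes (adjusted p = 0.017, and adjusted p = 0.367 with an estimated correlation) were called as lower. Among the 288 genes of the fixed block were 7 of 13 complement, 5 of 23 disease-associated microglia, 4 of 19 reactive astrocyte and 3 of 13 homeostatic microglia genes.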

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

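The tests of a larger lesion, of DNA of another strain, of a response to induced DKK1 as the whole cause of the intact-side differences, and of splits that keep the numbered pairs in the interaction without the block were chosen after the results were seen.

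By the interaction test the lesion response differed by genotype for H2-T-ps (log2 value 2.63). By the camera test of the interaction the lesion log2 change was higher in DKK1 mice for lists of T and NK cells (median 1.03), B and plasma cells (1.51), complement (0.82), disease-associated microglia (0.70), border macrophages and monocytes (0.70), and fibroblast and scar (0.67). It was also higher for interferon response (0.54), MHC (0.51), reactive astrocytes (0.42), homeostatic microglia (0.39), lipid handling (0.32), brain endothelium (0.23), Wnt/beta-catenin targets (0.21), mural cells (0.18) and blood-brain barrier (0.16). It was lower for thalamus and hypothalamus (−0.97), choroid plexus (−0.65) and hippocampus (−0.22), in part from the intact side, and for inhibitory neurons (−0.16) and neuron and synapse (−0.06), called lower in lesions of both genotypes. With an estimated correlation 0 of these lists passed.

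By camera 11 lists of immune cells and signals, scar, reactive astrocytes and endothelial activation were higher in lesions of DKK1 than of wild-type mice, though 0 of them passed with an estimated correlation (smallest adjusted p = 0.548 with an estimated correlation). A single library does not account for the camera calls, as all 11 stayed called higher whichever of the 6 lesioned libraries was left out. A thalamic share as measured by the thalamus and hypothalamus score does not either, since 11 stayed called with that score as a covariate. The score mixes thalamic and hypothalamic genes. It overlapped between the lesions of the genotypes, at 0.586 to 2.02 in wild-type and 0.606 to 1.77 in DKK1 mice. A different share of tissue in the samples is thus not excluded by this covariate. A larger lesion in the DKK1 mice stays open: the neuron list's median was −0.015, where the ratio seen in wild-type lesions needs −0.0686. The value needed lies within the 95% bootstrap interval of −0.0691 to 0.0189. The bootstrap resampled the genes of the list, which are not independent, so it does not cover the spread between libraries. A response to induced DKK1, which the design names, and other DNA of the DKK1 strain may each contribute and were not tested apart for these lists.

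Genes that differed by genotype on the intact side lay close together on the chromosomes, with 320 pairs within 1 Mb against at most 45 in 10000 permutations, and 10 Mb windows that held more such genes than chance gives held 71.0% of them and 36.5% of the genes called on the lesioned side. Reads shared between near-identical copies do not account for it as a whole, since 57 pairs of called genes lay within 1 Mb after pseudogenes and families were left out, against at most 16 in the permutations. A response to induced DKK1 and DNA of another strain linked along chromosomes both stay open. The count of pairs and that of genes on chromosome 17 (65 of the 155, against at most 30 in the permutations) are the pattern itself. Genes known to vary between strains bear on DNA of another strain, since Nnt (47.1 to 62.7 against 29.8 to 36.4 CPM) and H2-Ea-ps (19 to 1939 against 0 to 4 counts) were higher in every DKK1 than in every wild-type library, but the 4 other strain-variable genes measured did not pass, and single genes do not decide it for the set.

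Transcripts of liver cells were higher on the intact than on the lesioned side of wild-type mice. Liver RNA in some libraries is consistent with a second list of liver genes, not looked at before, of which 94.7% had their highest level in wild-type contralateral 1. A change of the brain tissue with the lesion stays open, as 42.1% of them were higher in every wild-type intact than in every wild-type lesioned library, between the bounds set for that test. That share cannot tell these explanations apart, since liver RNA in all wild-type intact libraries would also raise it. In DKK1 mice Alb, as an example, stood at 1.62 to 2.50 CPM on the intact and 2.16 to 3.01 CPM on the lesioned side. It thus did not fall with the lesion there.

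For the comparisons of 3 with 3 libraries the 10 splits are too few for a share under 0.05. The real splits gave 417 genes (lesioned side), 155 (intact side), 6546 (wild-type lesion) and 8819 (DKK1 lesion), and the highest other split gave 0 genes in each. For the interaction with the block the 10 splits of the numbered pairs are likewise too few, with 288 genes in the real split and 0 in the highest other. For the interaction without the block 4 of 100 relabellings of genotype, the real one included, gave at least the 1 real call. Such relabellings can part the numbered pairs, and the 10 splits that keep them are too few for a share under 0.05, with 1 gene in the real split and 0 in the highest other. The highest other relabelling gave 390 genes: it exchanged the genotypes of all intact-side libraries, so that it measured the genotype difference summed over hemispheres, a structure of the samples.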

How the results depend on the processing

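The alternatives without both wild-type libraries numbered 1, without genes in the genotype windows, with the number alone as a block and of fry with the block were chosen after seeing the data. For the named genes 2828 of 3205 values under alternatives kept direction and side of the threshold and 377 were no longer past it; for called lists these were 1008 and 225 of 1233, and 0 values of either kind reversed. The cause was not tested, except that fewer libraries or genes entered some fits. Genes called on the lesioned side (417) were 1188 by DESeq2 (403 of the 417 shared), 661 by limma-voom, 97 with the compared groups alone, and 655 with the replicate block as a random effect. They were 120 at an adjusted p under 0.01, 68 against a 1.5-fold change, 3244 without both wild-type libraries numbered 1, 62 without the window genes and 119 to 2551 with 1 library left out. Those on the intact side (155) were 285 by DESeq2, 95 under 0.01, 59 against 1.5-fold, 22 without the windows and 94 to 197 with 1 library out. Lesion calls fell to 3701 (wild type, 6546) under 0.01 and to 1532 and 2353 (DKK1, 8819) against 1.5-fold, and with 1 library out were 4457 to 6683 and 7316 to 8698. The interaction (1 gene) had 70 by DESeq2, 0 by limma-voom, 9 on TPM, 288 with the replicate block and 2 with it as a random effect. It had 2 with the number alone as a block, 0 under 0.01, 264 without both wild-type libraries numbered 1, 0 without the windows and 0 to 393 with 1 library out. Shared genotype calls (114) were 60 with the compared groups alone, 45 against 1.5-fold and 17 without the windows; shared lesion calls (5811) were 3407 under 0.01 and 1404 against 1.5-fold. The adjusted p of Dkk1 (0.0443, past 0.05 but not 0.01) was 0.0512 on TPM, 0.207 against 1.5-fold, 0.0681 without the windows and 0.0246 to 0.147 with 1 library out, and over all its alternatives 0.00573 to 0.207. DESeq2, the stricter filter and the fit of the compared groups gave it no value. Called lists were 0 in all 5 comparisons with an estimated correlation. By fry they were 6 (lesioned side, 16 by camera), 2 (intact, 5) and 0 (interaction, 20). By fry with the replicate block they were 4 (T and NK cells at 0.0519 and reactive astrocytes at 0.0559 lost), 1 (strain-variable genes at 0.059 lost) and 15. In wild-type lesions they were 30 by fry and 32 with the block, which added hippocampus (0.0027) and hypoxia (0.00325), and in DKK1 lesions 29 in both. On the intact side they were 8 with the replicate block and 1 to 10 with 1 library out, and in the interaction 12 to 23 with 1 library out. A fit of the compared groups alone was not run for the interaction, whose groups are all of those in the model. Beyond the calls given with a block in the report and the other observations, the replicate block changed no other camera call of a list, nor the call of a gene in a comparison where its test is given. Few counts limit genes such as Dkk1.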

Other observations

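Genes of neurogenesis and proliferation were called higher as a list in lesions of both genotypes. In wild-type mice 11 of 16 rose (13 adjusted over the list alone, median 0.71, adjusted p = 4.64e-05), among them the neural progenitor factor Eomes (4.63 ± 0.49) and the topoisomerase Top2a (1.66 ± 0.26). In DKK1 mice 11 of 16 rose (11 rose and 1 fell adjusted over the list alone) with adjusted p = 9.67e-04, among them Top2a (2.53 ± 0.28) and the proliferation marker Mki67 (2.04 ± 0.23). The values were adjusted p = 0.202 and 0.241 with an estimated correlation. The list was not called between the lesions of the genotypes (median 0.08, adjusted p = 0.646). The lists that follow were not called in either lesion comparison without a block. Of hypoxia and stress genes 4 of 18 rose and 2 fell (4 and 2 adjusted over the list alone, median 0.20, adjusted p = 0.298) in wild-type and 7 of 18 rose and 3 fell (7 and 3 adjusted over the list alone, median 0.33, adjusted p = 0.225) in DKK1 mice. With the genotype-by-number block this list was called in DKK1 mice (12 of 18 rose and 3 fell, adjusted p = 0.0287, and adjusted p = 0.156 with an estimated correlation). Of Wnt ligands, receptors and regulators 16 of 47 rose and 7 fell (18 and 9 adjusted over the list alone, median 0.19, adjusted p = 0.231) and 20 of 47 rose and 6 fell (20 and 6 adjusted over the list alone, median 0.21, adjusted p = 0.11). Immediate early genes had medians of −0.13 (adjusted p = 0.99) and 0.04 (0.967). Erythrocyte genes had medians of 0.21 (0.51) and −0.27 (0.936), and sex genes of 0.08 (0.51) and 0.08 (0.563). Between the lesioned hemispheres of the genotypes, excitatory neuron, hippocampus and ependymal genes were not called, with medians of −0.13, −0.20 and −0.22.

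On the lesioned side 265 genes outside the windows of clustered genotype differences passed, 180 higher and 85 lower in DKK1 mice. The 10 genes that follow were chosen after their values were seen. Higher were the B cell genes Cr2, a complement receptor (1.78 ± 0.31), and Btla (1.29 ± 0.25). The B cell genes Tnfrsf13c (from 2.19 ± 0.476 to 6.21 ± 1.82 CPM) and Bank1 (from 4.53 ± 0.561 to 9.68 ± 2.59 CPM) were higher too. So were the chemokine receptor Cxcr4 (0.93 ± 0.20), the secreted proteins Thbs1 (1.25 ± 0.26) and Clec3b (1.60 ± 0.20), the scavenger receptor Colec12 (1.37 ± 0.23) and the transcription factor Tfap2b (1.44 ± 0.18). The histamine receptor Hrh1 was lower (−0.58 ± 0.10). Clec3b and Tfap2b kept the call whichever library was left out. The other 8 lost it without wild-type ipsilateral 2 (adjusted p from 0.0682 to 0.148) or wild-type ipsilateral 3 (0.0521 to 0.158). Without DKK1 ipsilateral 2, Btla (0.0718), Colec12 (0.0553), Cxcr4 (0.164), Hrh1 (0.0649) and Thbs1 (0.0649) lost it. Without DKK1 ipsilateral 3, Bank1 (0.0656), Btla (0.121), Cr2 (0.0738), Cxcr4 (0.151), Thbs1 (0.0688) and Tnfrsf13c (0.126) did. With the genes of the windows left out of the adjustment, 62 of all genes passed, and Btla (0.0575), Tnfrsf13c (0.0575), Cxcr4 (0.0596) and Thbs1 (0.0581) did not, since their adjusted p rests on the share of small p among all genes tested. None of the 10 passed on the intact side. A difference between hemispheres did not pass for any of them by the interaction test (adjusted p from 0.311 to 0.605). With the genotype-by-number block as a fixed effect it passed for Btla (adjusted p = 0.0308), Thbs1 (0.0218) and Colec12 (0.0186), so it rests on the pairing of libraries by number, and with the block as a random effect 2 of all genes passed.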
